A study of Homo sapiens with 7 samples.

How the data were processed

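Total RNA of A549 cells was taken 48 h after transfection, 0.2 µg per array with an RNA integrity number of 9, and labelled with Cy3, per the labels' protocols. Each of the 7 samples, 4 with the control mimic and 3 with miR-223-3p, was hybridised to 1 array. The labels call the experiments of each group independent. The deposited scanner files hold the brightness of each spot as intensity on a linear scale, made with Agilent Feature Extraction 10.7.3.1, per the file headers. The processed signal in them is the spot's brightness after background subtraction and correction of spatial and multiplicative trends, with a surrogate value for dim spots, and it was not normalized between arrays, per the file headers. The authors' deposited series table holds log2 values. These differed from quantile-normalized log2 median spot intensities, without background subtraction, by a median of 0.0038, and from log2 processed signals by 1.97. Their rank correlation with the former was 1.00 on average over arrays, and column medians were 6.60 to 6.61. How the authors made this table is not given in the sources used here. It served only as an alternative.

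The 62976 spots of each array included 58717 that were not controls. Spots with an outlier flag were left out, control spots were left out, and the spots of a probe were averaged, which gave 50599 distinct probes, 902 of them with 10 spots. The log2 processed signal was reduced by each array's 75th percentile over probes. Probes well above background on at least 3 of the 7 arrays were kept, and the brightest probe by mean over the arrays stood for a gene. Gene names came from the RefSeq accession of 28174 probes, from a current symbol in the files for 2612 and from an older symbol for 607, and 2924 kept the symbol of the array design. The other 16282 probes had no symbol and were left out of gene counts. Of changed genes, 1706 had several probes and 90 of these had a called probe of opposite sign. For a gene not well above background on any array of one group, the fold is a lower bound, from the brighter group's mean and the mean, per array, of the higher of the dim probe's signal and the lowest signal among probes well above background. This applied to 312 genes. A fold change of a dim gene that is not given as a bound still includes background.

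The groups were compared with lmFit and eBayes in limma 3.58.1 (R 4.3.3) on the scaled log2 signals, two-sided, with Benjamini-Hochberg adjustment over 15394 genes and a threshold of 0.05. Errors of fold changes are limma's moderated SE. The 21 gene lists were tested together with camera, with its preset correlation of 0.01 between genes and again with an estimated one, and with Benjamini-Hochberg adjustment over the lists. The lists, the alternatives, the design and the rule for named genes were fixed before the data were examined. The lists held the literature targets of miR-223-3p, epithelial genes, mesenchymal genes, transcription factors of the epithelial-mesenchymal transition, TGF-beta response, type I interferon response, NF-kB and inflammation, cholesterol synthesis and uptake, G1/S and DNA replication, G2/M and mitosis, p53 targets, the unfolded protein response, the microRNA pathway, mRNA decay, insulin, IGF and FOXO signalling, hypoxia and glycolysis, NRF2 targets, alveolar and airway epithelium, cytosolic ribosomal proteins, and oxidative phosphorylation. The remaining list and some genes that the rule for named genes selects are not reported here, though the list stayed in the adjustment over 21. Of 615 measured members, 16 were on several lists. Genes named in the text are the 10 largest rises and 10 largest falls among changed genes whose groups did not overlap, leaving out loci that the files name as uncharacterised, up to 4 members of each list with the smallest adjusted p, and XRN1, CDH1, VIM, ZEB1, FN1, CDH2, FBXW7, RHOB, NFIA and STMN1 whatever their values.

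A planned search of 3' untranslated regions for miR-223-3p seed matches was not run, since transcript sequences were not used here. In its place the 60-base probe sequences were searched with Python 3.11.15 and numpy 2.4.6, and genes were grouped by the longest match in the probe. The difference of medians was compared with that of all 35 splits of the 7 arrays.

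The fit was tested on simulated data with known changes in the same 15394 genes. It recovered 35.8% of 67 genes changed 1.5-fold, 76.1% of 67 changed 2-fold and 95.5% of 66 changed 4-fold, with 8 calls among unchanged genes. Far fewer genes were changed in the simulation than differed in the data. The adjustment depends on that share, so these rates may not carry over to the data. In simulated lists camera ranked the shifted list at position 1 and called 0 of 20 unshifted lists. The simulated genes were drawn independently, so this does not test camera where genes are correlated. Alternatives were normexp background correction with an offset of 50, quantile normalization, median centring, the authors' values, no filter and a stricter filter on dim probes, the mean of a gene's probes, every probe, an intensity trend or robust variance in eBayes, the replicate number as a term, a minimum change of 1.5-fold, each array left out in turn, and, for lists, an estimated correlation, the rotation test fry and 10000 random lists matched on signal level, the last chosen after seeing the data. An alternative counted as a change of direction only where the result passed its threshold in at least 1 of the fits compared. Markers of leukocytes, erythroid cells, fibroblasts, endothelium and A549 itself were checked for admixture.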

Results

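A549, an epithelial cell line from a human lung adenocarcinoma, was transfected with a mimic of the microRNA miR-223-3p or with a control mimic, and RNA was profiled 48 h later on 1-colour Agilent gene expression arrays. A mimic is a synthetic double-stranded RNA that supplies a mature microRNA to the cell, and miR-223-3p is a microRNA best known from myeloid cells. The labels give 4 independent experiments with the control mimic and 3 with miR-223-3p. Each array carried 50599 distinct 60-base probes outside its controls. Between 48.0% and 51.3% of these probes were well above background on the control arrays and between 46.2% and 46.8% on the miR-223-3p arrays, and no probe was saturated. After scaling, correlations across genes were 0.988 to 0.996 among control arrays, 0.990 to 0.991 among miR-223-3p arrays and 0.967 to 0.975 between the groups. The number of arrays limits the precision of every value given here. The title of the series names the decay of extracellular microRNA by the exonuclease XRN1 and a transient epithelial-mesenchymal transition, the loss of epithelial for mesenchymal features, and the comparison asks which transcripts differed after the miR-223-3p mimic.

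Transcripts that earlier literature named as targets of miR-223-3p fell as a group. STMN1, which encodes the microtubule-destabilising protein stathmin, fell 10.2-fold at the brightest of its 2 probes, on chromosome 1 from 26227232 to 26227291 of the GRCh37 build (log2 fold change -3.36 ± 0.10, SE, n = 3 against 4, limma adjusted p = 4.34e-06), and by 0.97 on the log2 scale at the other, with -2.16 for the mean of both. NFIA, a transcription factor, fell 3.66-fold at the brightest of its 2 probes (-1.87 ± 0.13, adjusted p = 6.53e-05) and by 1.17 on the log2 scale at the other, and RCN2, a calcium-binding protein of the endoplasmic reticulum, fell 3.53-fold (-1.82 ± 0.12, adjusted p = 4.87e-05). LMO2, a transcriptional cofactor of blood cell development, was not well above background on any miR-223-3p array and was at least 1.98-fold lower (adjusted p = 1.03e-05), with a log2 fold change of -0.93 with normexp background correction. RHOB, a small GTPase, fell 2.03-fold and FBXW7, the substrate-binding part of a ubiquitin ligase, fell 1.57-fold (adjusted p = 0.00101 and 0.00489). Of the 28 measured members of the list, 17 fell, 3 rose and 8 did not pass the test, and 18 fell and 3 rose when adjusted over the list alone. The members that rose were ATM, LIF and STAT3, named after their values were seen, with log2 fold changes of 0.48, 0.51 and 0.55. The median log2 fold change of the list was -0.72, a shift that camera, limma's competitive test of a gene list, called with an adjusted p of 9.73e-07, and with an adjusted p = 0.0344 with an estimated correlation. The list was drawn from earlier literature and fixed before the data were examined, not taken from these arrays.

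**Figure D1:**
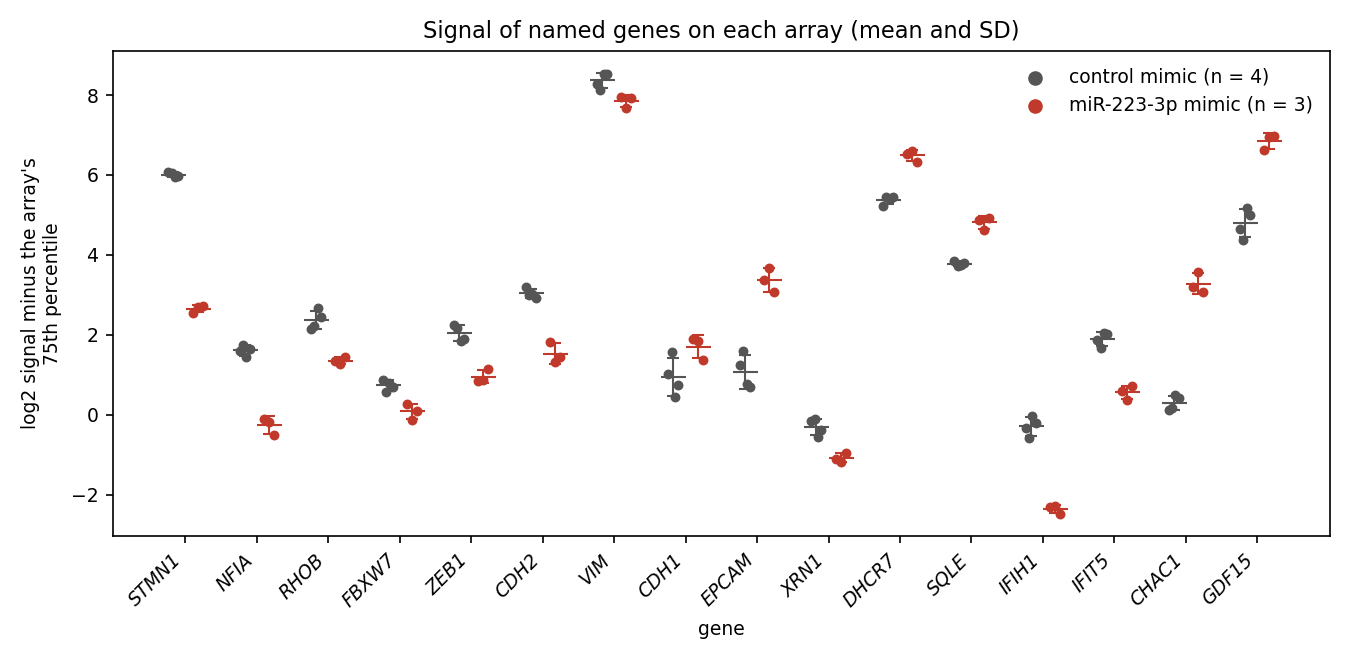
Signal of 16 named genes on each array, as log2 signal minus the array's 75th percentile. Grey points are the 4 control mimic arrays and red points the 3 miR-223-3p mimic arrays, with the mean and SD of each group. STMN1 lay at 6.01 on average with the control mimic and at 2.66 with miR-223-3p, while the arrays of both groups overlapped for CDH1.

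Genes whose probe contained a longer match to the miR-223-3p seed were also lower as a group, though not for each type of match. The seed is the stretch of a microRNA, at positions 2 to 8, that pairs with its targets. The 21 genes whose 60-base probe held the longest match, the 8mer AACTGACA, had a median log2 fold change of -0.55, with 13 lower and 0 higher in limma at an adjusted p under 0.05 and 15 lower and 1 higher at an unadjusted p under 0.05. For the 52 genes with the 7mer-A1 match ACTGACA, the median was -0.41, with 23 lower and 3 higher. The 39 genes with the 7mer-m8 match AACTGAC had a median of -0.08, with 16 lower and 7 higher. The 91 genes with a 6mer match had a median of -0.09, with 24 lower and 17 higher. For the 15191 genes with no match the median was 0.05, with 2820 lower (18.6%) and 3144 higher (20.7%). The share lower was 61.9% for the 8mer, 44.2% for the 7mer-A1, 41.0% for the 7mer-m8 and 26.4% for the 6mer. The share higher was 17.9% for the 7mer-m8 and 18.7% for the 6mer, near that of genes with no match. The median of 60 genes with an 8mer or 7mer-m8 match lay below that of genes with no match by a difference of -0.39 (exact permutation test over the 35 splits of the arrays, two-sided, p = 0.0286, the smallest these splits can give). For the 7mer-m8 genes alone the difference was -0.12 and was not past the threshold (exact permutation p = 0.114). Among 11714 words of 7 bases found in at least 20 genes' probes, ACTGACA was the one with the lowest ranks of fold change. AACTGAC held position 7 from the lowest. These words were counted in 73 and 60 genes, which include the 21 genes with the 8mer, so their positions rest in part on the 8mer. The reverse complement of the 7mer-m8 match, GTCAGTT, held position 10805, and the match of the other strand of the precursor, miR-223-5p, held position 7978. This search used the probe sequences, chosen after it was clear that 3' untranslated regions were not part of the reference used here, and sees only a short part of each transcript.

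**Figure D2:**
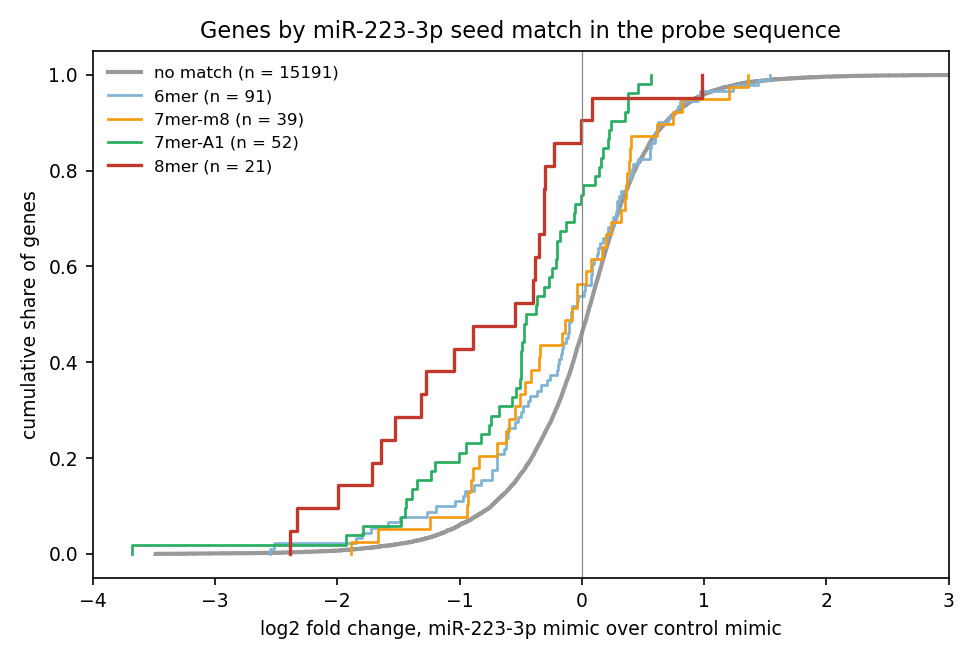
Cumulative share of genes (vertical axis) by log2 fold change of miR-223-3p over control mimic (horizontal axis), for genes whose probe held an 8mer, 7mer-A1, 7mer-m8 or 6mer match to the miR-223-3p seed or none. The curve of the 21 genes with an 8mer, with a median of -0.55, lies to the left of that of the 15191 genes with no match, with a median of 0.05.

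Most genes of cholesterol synthesis and uptake were higher with miR-223-3p. DHCR7, SQLE and FDFT1, which encode enzymes of the sterol pathway, rose by log2 fold changes of 1.11 ± 0.11, 1.04 ± 0.11 and 0.92 ± 0.10 (SE, n = 3 against 4), with limma adjusted p-values of 0.000242, 0.000279 and 0.000265. Of the 27 measured members, 18 rose, 2 fell (PMVK and LBR, named after their values were seen) and 7 did not pass the test, and 19 rose and 2 fell when adjusted over the list alone. The median log2 fold change was 0.62 and the camera adjusted p was 0.000148. This call was lost when camera estimated the correlation (camera adjusted p = 0.166), which came to 0.033 for this list. The same setting raised the unadjusted camera p of the literature targets from 4.63e-08 to 0.00164, although their estimated correlation was -0.024. The loss therefore cannot be put down to correlation between the cholesterol genes alone.

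Among genes of the type I interferon response, the antiviral programme, more were lower than higher. IFIH1, a sensor of double-stranded RNA, fell 4.19-fold (-2.07 ± 0.14, adjusted p = 6.04e-05), IFIT5 fell 2.54-fold (-1.34 ± 0.13, adjusted p = 0.000204), SAMD9L fell 3.18-fold (-1.67 ± 0.18, adjusted p = 0.000279) and OASL was at least 1.70-fold lower, since it was not well above background on any miR-223-3p array. With normexp background correction these log2 fold changes were smaller, at -1.46 for IFIH1, -1.04 for SAMD9L and -0.65 for OASL. Of the 35 measured members, 15 fell, 5 rose and 15 did not pass the test, and 16 fell and 6 rose when adjusted over the list alone. IRF9, EIF2AK2, IRF7 and OAS3, named after their values were seen, were among the 5 that rose. The median log2 fold change was -0.40 with a camera adjusted p of 0.0274. The call did not hold with an estimated correlation (adjusted p = 0.435 with an estimated correlation), with normexp background correction (adjusted p = 0.0614), quantile normalization (0.0527), median centring (0.0536), the authors' values (0.0901), probes well above background on every array (0.0736), or without miR-223-3p replicate 3 (0.0563).

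Genes that mark the epithelial and mesenchymal states moved in both directions, and camera called neither list as shifted. Among epithelial genes, EPCAM, a cell adhesion molecule, rose 4.91-fold (2.30 ± 0.24, adjusted p = 0.000298) and the tight junction protein gene TJP1 rose 2.02-fold. The claudin gene CLDN4 fell 3.88-fold (-1.96 ± 0.17, adjusted p = 0.000112). CTNND1, which encodes p120 catenin, fell 2.17-fold at the brightest of its 2 probes and by 0.64 on the log2 scale at the other. The E-cadherin gene CDH1 had a log2 fold change of 0.76 ± 0.26 with an adjusted p of 0.0470, a call that was lost under 8 of 17 other settings. Of 25 measured epithelial genes, 9 rose, 4 fell and 12 did not pass the test, 9 rose and 5 fell when adjusted over the list alone, and the median was 0.21 (camera adjusted p = 0.732). Among mesenchymal genes, CDH2, which encodes N-cadherin, fell 2.85-fold (-1.51 ± 0.14, adjusted p = 0.000161), and SPARC, the gene of a secreted matrix-associated protein, fell by 1.02 on the log2 scale. VIM, the gene of the intermediate filament vimentin, fell by 0.52 ± 0.13 (adjusted p = 0.0163; 0.0588 without miR-223-3p replicate 2), and the collagen gene COL1A1 rose by 1.19. The fibronectin gene FN1 had a log2 fold change of -0.33 ± 0.34 (adjusted p = 0.466). Of 26 measured mesenchymal genes, 4 rose, 9 fell and 13 did not pass the test, 5 rose and 9 fell when adjusted over the list alone, and the median was -0.17 (camera adjusted p = 0.361). Of random lists matched on signal level, 0.82% had a median as low as the mesenchymal list and 4.03% one as high as the epithelial list. After adjustment over the lists, neither was called under any of 20 other settings, these random lists included. A smaller shift is not ruled out.

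Of the transcription factors that drive the epithelial-mesenchymal transition, ZEB1 fell 2.12-fold (-1.09 ± 0.14, adjusted p = 0.000700), SNAI1 rose 1.61-fold (0.69 ± 0.13, adjusted p = 0.00363), and KLF8 had a log2 fold change of -1.16 with an adjusted p of 0.0598. The probes of ZEB2 disagreed, since its brightest probe rose by 1.21 and another fell by 1.83 on the log2 scale, and the mean of its 3 probes gave -0.13 with an adjusted p of 0.474. Of 12 measured factors, 2 rose (SNAI1 and, by its brightest probe only, ZEB2), 1 fell and 9 did not pass the test, and 2 rose and 1 fell when adjusted over the list alone (median -0.08, camera adjusted p = 0.994). For this list the median and mean were negative while the test's sign was positive. XRN1, the exonuclease named in the title, measured by a probe on chromosome 3 from 142025612 to 142025671, fell by 0.78 ± 0.13 on the log2 scale (1.72-fold, adjusted p = 0.00260), and the 37 measured genes of mRNA decay split into 7 higher, 7 lower and 23 not passing, 7 and 7 when adjusted over the list alone (median 0.11, camera adjusted p = 0.887). In that list DCP2, which encodes the decapping enzyme, rose by 1.25. CNOT7 fell by 0.98 at the brightest of its 2 probes and by 0.63 at the other, and EDC4 fell by 0.93 at its brightest probe.

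**Figure D3:**
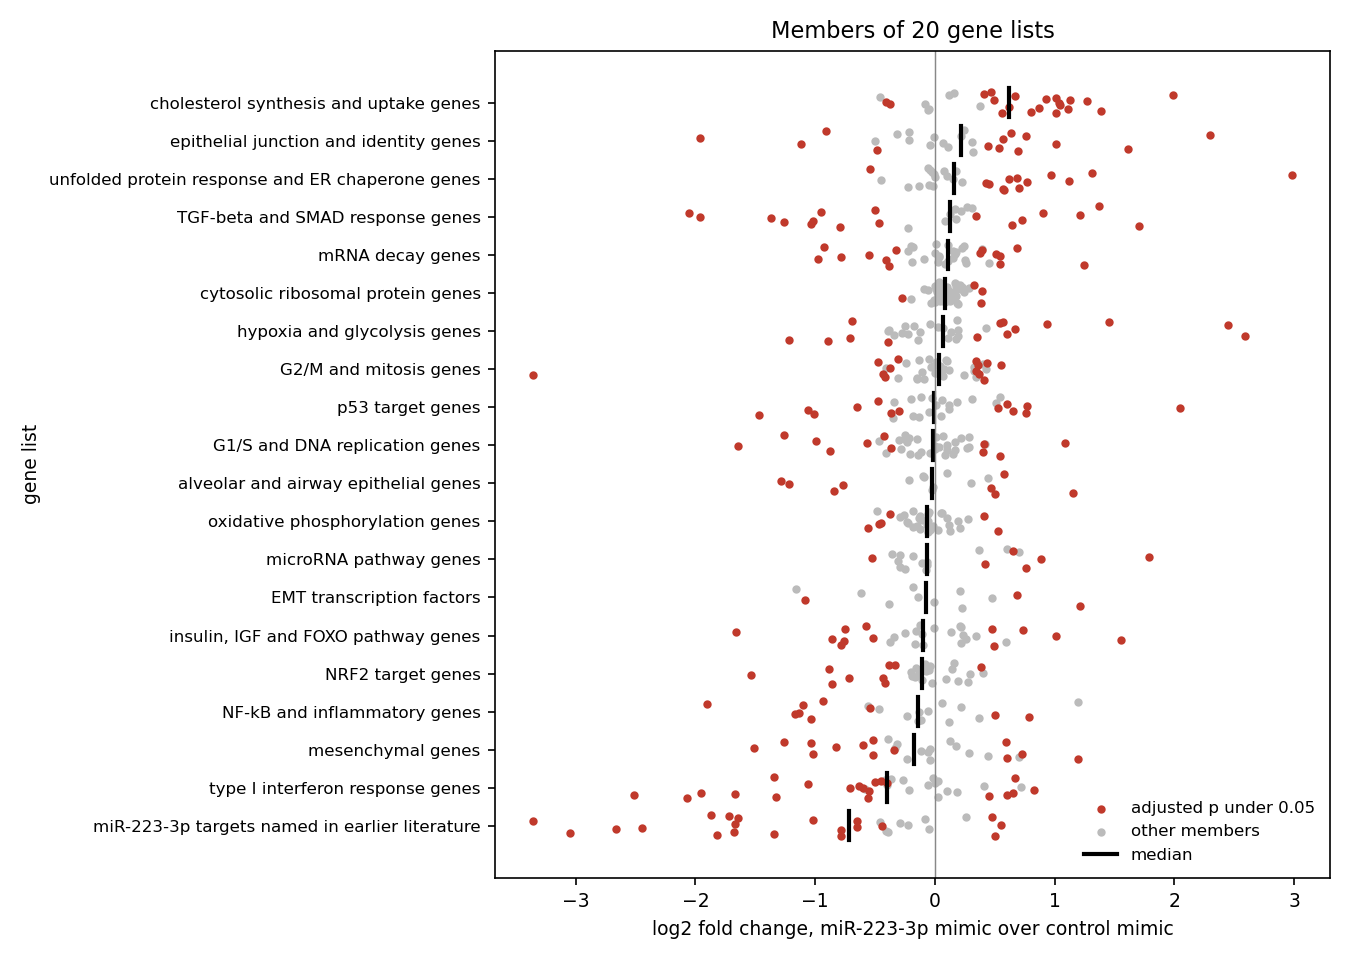
Log2 fold change of miR-223-3p over control mimic (horizontal axis) for each measured member of 20 gene lists (vertical axis). Red points passed an adjusted p under 0.05 in limma, grey points did not, and black bars mark the medians, which ran from -0.72 for the literature targets to 0.62 for the cholesterol genes.

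The largest changes of single genes went both ways. The 10 largest rises and falls were ranked by the processed signal, and where a gene was not well above background in one group its rank rests on background. Of the 10 rises, those measured in both groups were CREB5, a transcription factor, at 9.90-fold (3.31 ± 0.38), on 2 of 4 control arrays, DHRS9, a retinol dehydrogenase, at 8.95-fold (3.16 ± 0.23), CHAC1, a glutathione-degrading enzyme, at 7.90-fold (2.98 ± 0.15) and PGF, placental growth factor, at 7.67-fold (2.94 ± 0.18). IL21R, CABP7, BCL2L10, CDH26, NAV2-AS4 and NKD1 were not well above background on any control array and were at least 6.95-fold, 5.68-fold, 4.15-fold, 3.95-fold, 3.05-fold and 2.15-fold higher, so the last 4 of these bounds lie below the 4.91-fold rise of EPCAM. Of the 10 falls, STMN1 is given above, and CD109, a membrane-anchored co-receptor, fell 9.48-fold (-3.24 ± 0.15), NF2, the tumour suppressor merlin, 9.09-fold (-3.18 ± 0.18), CLDN2, a claudin, 8.32-fold (-3.06 ± 0.34) and CD59, a complement inhibitor, 7.96-fold (-2.99 ± 0.16). PDZK1, C4BPB, SAA1 and ITGB6, like LMO2, were not well above background on any miR-223-3p array and were at least 7.17-fold, 3.37-fold, 2.86-fold and 2.59-fold lower, and the bounds of LMO2, C4BPB, SAA1 and ITGB6 lie below the 3.66-fold, 3.88-fold and 4.19-fold falls of NFIA, CLDN4 and IFIH1. NF2 had 2 probes, of which the brightest gave the value above, while the other fell by 1.89 on the log2 scale and the mean of both was -2.54. With normexp background correction, changes of dim genes were smaller, at 1.52 for CREB5, 1.91 for DHRS9 and -2.25 for CD59, from 0.87 for NKD1 to 1.61 for IL21R among the rises given as bounds, and from -1.61 for PDZK1 to -0.92 for ITGB6 among the falls. For every gene given here as a bound, OASL included, the normexp change was smaller in size than the bound. The offset added with that correction shrinks the changes of dim genes by construction, so this comparison cannot test the bounds. They are given for the processed signal only.

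Across all genes, 6067 of 15394 (39.4%) differed (limma, adjusted p under 0.05), with 3171 higher and 2896 lower. By fitted values, at least a 2-fold change was reached by 597 higher and 921 lower genes. These counts include genes given only as a bound, such as LMO2 and OASL, whose bounds lie below 2-fold. The arrays of both groups did not overlap for 7095 genes (46.1%, against 5.71% by chance), among them 5874 of the changed genes and every gene given above as changed except CDH1 and IRF9. When each array was centred on its median, the median log2 fold change of all genes moved from 0.04 to -0.09, and 2070 of 5896 changed genes were higher (35.1%, against 52.3%), so that the balance between higher and lower genes followed the scaling. Without a filter on dim probes, 6307 genes were higher and 2702 lower. All arrays lay on 1 slide scanned once, controls in row 1 and miR-223-3p in row 2, so slide row and group cannot be told apart.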

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

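The tests of the slide rows and of random lists were chosen after the results were seen. The search of probe sequences was chosen after seeing the data files, in place of the planned one, but before any fold change of genes with a match was seen, and the count of splits was planned.

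The lower levels of genes with a seed match in the probe may reflect direct action of the mimic on transcripts that carry the match. The difference of medians, -0.39, fits that account, and 99.7% of the 315 other words with the same bases lay above the 7mer-m8 match, which argues against base composition of the probes. Of the 35 splits of the arrays, 1, the real one, gave a difference as large in size, a share under the 0.05 level set beforehand. The splits relabel arrays and keep the genes fixed, so they cannot exclude chance in which genes carry the match. The highest of the other splits was 0.346. Other splits can keep part of the difference between treatments, so this is not a value under chance alone. Words rich in A and T were low too, such as AAAATAA at position 2 of 11714 from the lowest, so part of the low ranks near the seed matches stays unexplained. Literature targets with no match in the probe also fell, 15 of 26.

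The 6067 changed genes were not matched by any other split. Of the 35 splits of the arrays, 1, the real one, gave as many, and the highest of the others was 1 gene. Every other split puts arrays of both treatments into at least 1 group, so a difference between treatments widens the spread there and leaves few calls. The count argues against chance only as far as 1 in 35. The groups lay in different slide rows, and an additive difference in background between rows is a candidate explanation. For the brightest eighth of genes it is argued against, since 2.75% of them changed at least 2-fold, where an offset would move a bright signal little. For the dimmest eighth, 64.6% of such changes were lower, between the bounds set for a background offset and against it, so it cannot be told apart from an effect of the mimic there. The filter can also tilt this share towards lower. A gene dim in the other group passed it with 3 of 4 control arrays but needed all 3 miR-223-3p arrays. Without a filter the median log2 fold change of all genes was 0.20, and the lowest processed signals of a probe, on the linear scale, were 4.24 to 4.57 on control arrays and 5.84 to 6.30 on miR-223-3p arrays. A difference between rows in proportion to the signal would move all genes alike and is removed by the scaling, so it does not account for the 3171 higher and 2896 lower genes. A difference between rows that varies from probe to probe, as in hybridisation, was not tested and stays open.

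The shifts of the cholesterol and interferon genes were weighed against a trend of fold change with signal level. Among 10000 random lists matched on signal level, 0% had a median as high as that of the cholesterol genes and 0.01% one as low as that of the interferon genes, which argues against such a trend. These random lists treat genes as independent, and the loss of both calls with an estimated correlation, given in the account of the lists, stays beside them. That setting also raised the p of the literature targets, whose estimated correlation was negative, so neither loss can be put down to correlation alone. The 3 cholesterol genes that are also on the target list, HMGCS1, MSMO1 and SCARB1, had log2 fold changes between -0.46 and -0.05 and 0 of them passed the test in limma, or an unadjusted p under 0.05, whereas 18 of the other 24 rose. That these genes differ from the rest of their pathway was not tested.

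A control array far from the other 3 was seen for 4 of 102 named genes, where chance gives about 1 in 20. The gap to the nearest array, as a share of the range, was 0.853 for DHCR7 (replicate 1 lowest, at 5.21 against 5.41 to 5.44), 0.920 for DICER1 (replicate 4 lowest), 0.888 for NF2 (replicate 2 lowest, at 5.02 against 5.60 to 5.67) and 0.879 for RCN2 (replicate 3 highest). Control replicate 1 had 288 spots with an outlier flag, with a gap of 0.930. Among probes with no gene symbol, which the gene counts leave out, 683 of 3386 changed (limma), 245 higher and 438 lower.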

How the results depend on the processing

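The seed-match search of probes, with its settings, and the random lists were added after seeing the data, and the other settings were planned. The shift of the literature targets was called and negative under all 20 other settings, with medians of -0.86 to -0.52, and that of the cholesterol genes under 19 of 20, with medians of 0.48 to 0.67; with an estimated correlation its median of 0.62 was not called. The median of the interferon genes stayed negative, but the call was lost with normexp (-0.27), quantile normalization (-0.39), median centring (-0.53), the authors' values (-0.25), the filter on every array (-0.37) and an estimated correlation (-0.40), and the medians with 1 array left out ranged from -0.43 to -0.32, with the call lost without miR-223-3p replicate 3; the cause was not tested. Lists not called otherwise were called without a filter, which adds dim genes to the comparison, namely G1/S (-0.020), NRF2 (-0.096) and oxidative phosphorylation (-0.063), and with fry, which does not compare a list with other genes, the unfolded protein response (0.16), hypoxia (0.071), oxidative phosphorylation (-0.063) and G2/M, whose test turned negative (median 0.032); against random lists NRF2 was called (-0.11). Some medians turned sign. That of the mesenchymal genes was 0.048 with no filter (main -0.17) and that of the factors of the epithelial-mesenchymal transition 0.10 with the filter on every array (main -0.076). With median centring it was negative for the ribosomal, hypoxia, mRNA decay, TGF-beta and G2/M lists (-0.10 to -0.0083), for TGF-beta also without miR-223-3p replicate 1 (-0.019), and for G2/M under 4 more settings (-0.020 to -0.00050). It was positive for the p53 list with the authors' values (0.0048), the replicate block and without control replicate 4 (0.039 each), for G1/S without control replicate 1 (0.0073), and for the alveolar list under 7 settings (0.0030 to 0.14). Camera called none of these lists under these settings, and the cause was not tested. The count of changed genes was 4869 to 6358 under other settings except no filter (9009 of 23720 genes), every probe (7847) and the 1.5-fold minimum, which by construction left 3823, 1833 of them higher. Genes higher were 2070 with median centring and 6307 with no filter. Under the normexp correction 5632 of the 6067 changed genes were shared, and under median centring 4966. With the replicate block, 5843 genes changed. Deviations of arrays with the same replicate number correlated at 0.04, 0.36 and 0.29, and 0.36 and 0.29 were the highest of all pairs between groups. For miR-223-3p replicate 1 the highest was 0.06, with control replicate 3, hardly above the 0.04 of its own number. The number is also the slide column, so paired samples and an effect of the column cannot be told apart. The labels state no block, and the numbers were not taken to pair the samples. The seed-match difference was -0.42 with the replicate block and -0.42 to -0.33 with 1 array left out, where the 15 to 20 splits, or 8 swaps, cannot give a p under 0.05; the 7mer-m8 match alone gave -0.12 (exact permutation p = 0.114), and the cause was not tested. Of 102 named genes, 100 were called and 90 of these kept the call and its direction under every setting that tested them; the others included CDH1, VIM, FOXA2, FOXO4, ZEB2 (-0.13 with the mean of its probes, which point both ways) and the ribosomal genes RPL17, RPL22, RPL29 and RPS15. Of 2 uncalled genes, KLF8 was called under 5 settings and FN1 under 1. The searches of the longest or length-matched 3' untranslated region were not run. Signal over background limits genes not well above it in one group, 312 of them, to a bound.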

Other observations

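Several stress and growth genes changed strongly although camera did not call their lists. Over all 15394 genes 39.4% differed, 3171 higher and 2896 lower, so a count of called members near that share does not set a list apart. In the unfolded protein response, CHAC1 rose 7.90-fold, DDIT3, the transcription factor CHOP, rose 2.48-fold, DNAJB9, a chaperone cofactor, rose 2.17-fold and SESN2, a stress-induced regulator of growth signalling, rose 1.70-fold; 12 of 28 measured members rose and 1, PPP1R15A, named after its value was seen, fell, 12 and 1 when adjusted over the list alone (median 0.16, camera adjusted p = 0.0707). Of 30 p53 targets, 6 rose and 7 fell, with GDF15, a stress-induced cytokine, up by 2.05 and MDM2, the ligase that restrains p53, down by 1.47 on the log2 scale at the brightest of its 4 probes and by 0.49 at the least changed one (adjusted p of the list 0.887). In hypoxia and glycolysis, 9 of 33 rose and 5 fell (adjusted p = 0.887), with the glucose transporter gene SLC2A3 at 2.59, the aldolase gene ALDOC at 2.45 (1.42 and 1.44 with normexp background correction) and NDRG1 at -1.21. In the microRNA pathway, 5 of 19 rose and 1 fell (adjusted p = 0.887), among them LIN28B, an inhibitor of let-7 maturation, at 1.79 and DICER1, which cuts microRNA precursors, at 0.89.

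Growth and structural lists also held called genes of both directions, to be read against the 39.4% of all genes that differed. In G1/S and DNA replication, 4 of 40 rose and 7 fell (adjusted p = 0.418), with the cell cycle transcription factors E2F1 and E2F2 at -1.65 and -1.26 and the phosphatase CDC25A at 1.08. In G2/M and mitosis, 7 of 40 rose and 6 fell (adjusted p = 0.994), with STMN1 the largest fall, by its brightest probe, and the kinase gene TTK at 0.55. Of 29 insulin, IGF and FOXO genes, 5 rose and 7 fell (adjusted p = 0.887), with the kinase gene SGK1 at 1.55 and IGFBP2 at -0.75. Of 25 TGF-beta response genes, 7 rose and 10 fell (adjusted p = 0.887), with HDAC1 at 1.21 and JUNB at -1.96. NF-kB and inflammatory genes had 2 of 21 higher and 7 lower (adjusted p = 0.264), with TNFAIP2 at -1.04, and NRF2 targets 1 of 27 higher and 8 lower (adjusted p = 0.264), with the quinone reductase gene NQO1 at -1.54. Alveolar and airway genes had 4 of 16 higher and 4 lower (adjusted p = 0.973), with ABCA3 at -1.22 and NAPSA at 1.16. Ribosomal protein genes had 3 of 56 higher and 1 lower (adjusted p = 0.326), and oxidative phosphorylation genes 2 of 35 higher and 4 lower (adjusted p = 0.361). When adjusted over the list alone, 8 TGF-beta genes rose and 10 fell, 6 G2/M genes rose and 5 fell, 1 oxidative phosphorylation gene rose and 3 fell, and 0 ribosomal genes passed either way in limma, against 4 higher and 1 lower at an unadjusted p under 0.05; the counts of the other lists here were as over all genes. The median and mean differed in sign for the TGF-beta, G2/M, p53 and microRNA lists, with a positive camera test for G2/M and microRNA and a negative one for TGF-beta and p53.

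None of the 6 genes typical of A549 (ALDH3A1, ALDH1A1, AKR1B10, AKR1C1, KRT8 and KRT18) passed the test in limma, and 1 was lower at an unadjusted p under 0.05. Of 28 markers of leukocytes, erythroid cells, fibroblasts and endothelium, 7 passed the filter on dim probes and were tested. HBA2, COL1A1 and CDH5 rose, HBD and ITGAM fell, and PTPRC and CD14 did not pass the test. HBA2, HBD, PTPRC and CDH5 were dim, with mean processed signals between 12.8 and 57.3 in either group. HBA2, HBD and PTPRC were well above background on only 4, 3 and 3 of the 7 arrays, so their changes rest in part on background.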
